A study of Homo sapiens with 4 samples.

How the data were processed

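Total RNA was sequenced from cultures labelled with the ovarian cancer cell lines SKOV3 and OVCAR3, each as mock control cells and as cells with a CRISPR-Cas9 knockout of the envelope (env) gene of the endogenous retrovirus HERV-K119. The 4 groups (SKOV3 mock, SKOV3 KO, OVCAR3 mock, OVCAR3 KO) held 1 library each, and groups were taken from the sample titles. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with the NEBNext Ultra II Directional kit, which keeps the strand of the RNA. Per the submitters' processing notes, TopHat and the genome build GRCh38 were used. The counting tool, the annotation release and the strand setting are not given in the sources used here.

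The deposited values are raw counts of reads per gene symbol, whole numbers that were not normalised. Each table held 58173 rows with 52402 different symbols. The 2687 symbols that stood in several rows (8458 rows, between 0.351% and 0.465% of a library's counts) were summed. No row named anything other than a gene. Total counts were 22057693 for SKOV3 mock, 15145483 for SKOV3 KO, 16298490 for OVCAR3 mock and 15825915 for OVCAR3 KO. A count of 0 allows up to 3 counts, which is between 0.136 and 0.198 CPM (counts scaled to library size). Reads carried no molecular identifiers, so intervals and floors cover counting error only. Symbols were matched to a RefSeq table of GRCh38.p14 for gene type and chromosome, which found 85.2% of them, and GC content and length were taken from the longest GENCODE 29 transcript of a gene. Coordinates printed for a gene are from that RefSeq table.

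Counts were scaled by effective library sizes from the trimmed mean of M values (TMM) of edgeR 4.0.16 in R 4.3.3, with factors of 1.02, 1.04, 1.00 and 0.928 in the order above, and CPM below are scaled in this way. Within each line the log2 ratio of knockout over mock was computed with a prior count of 2. With 1 library per group there is no replicate check within a line and no p-value is given there. A gene was counted as higher or lower by a rule of size, an absolute log2 ratio of at least 1 with CPM of at least 1 in at least 1 of the 2 libraries. Each ratio of a named gene carries an exact 95% interval (from Clopper-Pearson bounds) of the ratio of the counts, without the prior count. The number of genes past the rule from counting error alone was drawn 100 times from Poisson counts. The cell line was the only replicate of the knockout: edgeR's quasi-likelihood test was fitted over all 4 libraries with the line as a block, on 13670 genes with CPM of at least 1 in at least 2 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. It has 1 residual degree of freedom per gene, and the same fit gave the difference between the lines. Nothing beyond the labels says how the cultures were kept apart, so the p-values measure the spread between these libraries.

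Before the data were examined, 41 gene lists (pathways, complexes, cell-type markers and genes that distinguish the lines) were fixed. In each line a list's median log2 ratio was placed among 10000 random lists of the same size matched on mean expression, and a median below the 2.5 or above the 97.5 percentile was called low or high, as a description of these libraries. Lists needed 5 measured members. Over both lines, lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and at an estimated one, and with fry. Named genes followed a rule fixed at the same time. Per line it took the 10 largest and 10 smallest log2 ratios among genes with a summed count of at least 100 and CPM of at least 5, without uncharacterised, antisense and small RNA symbols. Over both lines it took the 10 genes per direction with the largest smaller ratio. It also took RB1, CCNB1, NUPR1, the endogenous retrovirus members above the floor and up to 4 members of each list that was low or high. Genes that distinguish the lines, NEAT1, genes called by a test and genes past the size rule downward in both lines were named in addition, after the data were seen.

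The alternatives fixed beforehand were DESeq2 1.42.0 size factors and no scaling factor, no filter and CPM of at least 5, prior counts of 0.5 and 5, folds of 1.5 and 3, DESeq2, limma-voom and robust edgeR in place of the main test, and no block. Added after seeing the data were the removal of a spline trend (5 degrees of freedom) on GC content and length from the log2 ratios of protein-coding genes, random lists matched on GC content too, the mitochondrial rows left out, and the OVCAR3 KO library left out. The methods were tested on simulated counts with the means and library sizes of the 13670 genes and 200 genes changed in both lines. At the dispersion of these data, 0.127, edgeR recovered 0% of 2-fold, 40% of 4-fold and 99% of 16-fold changes. This dispersion holds the spread between the lines and was applied to all 4 libraries. In the 2-fold run 18.7% of unchanged genes passed the size rule in SKOV3, against 208 of 13524 measured genes in the data. The runs thus give SKOV3 more spread than it had. False calls in these runs numbered 0, 0 and 5. At a dispersion of 0.01 it recovered 92.5% of the 2-fold changes, and false calls numbered 10, 9 and 18 at 2-, 4- and 16-fold. The targeted provirus was not analysed here.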

Results

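RNA-seq counts were analysed for 4 libraries from cultures labelled SKOV3 and OVCAR3, human ovarian cancer lines, each as mock control and as knockout (KO) of the envelope gene of HERV-K119, a provirus of the HERV-K family of endogenous retroviruses. All cultures were treated with hygromycin after transfection, per the labels. There was 1 library per group, with total counts between 15145483 and 22057693. The design asks which transcripts differ between knockout and mock cells of each line, and whether the difference is alike in both. Ratios are log2 of knockout over mock with a prior count of 2, brackets give exact 95% counting intervals, levels are scaled CPM, and no difference within a line has a replicate check.

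The targeted HERV-K119 provirus was not analysed here, so its knockout was not checked at the RNA level. Among named endogenous retrovirus genes with enough counts, the SKOV3-labelled pair showed little difference. ERVK3-1, a HERV-K-related locus (chromosome 19, 58305377 to 58316812), had 35.2 CPM in the knockout and 32.3 in the mock library, a log2 ratio of 0.13 (-0.04 to 0.29), and ERVMER34-1, which encodes an envelope-derived protein, had -0.02 (-0.24 to 0.19). In the OVCAR3-labelled pair ERVK13-1, a long non-coding RNA locus on chromosome 16, was higher at 12.1 against 1.53 CPM (2.90, 2.38 to 3.66), as was ERV3-1, at 9.87 against 1.89 CPM (2.31, 1.82 to 2.99). ERVK3-1 was lower there, at -0.75 (-1.01 to -0.50), and so was ERVMER34-1, at -0.47 (-0.78 to -0.18). Over the list of endogenous retrovirus loci, 5 of 7 measured members passed the size rule upward in OVCAR3, as did 3387 of all 15409 measured genes. The median of 2.31 lay within the middle 95% of random lists matched on expression, and at percentile 99.5 of lists matched on GC content too. Matching on GC content also left out genes without a GC value and used coarser expression groups, so the 2 percentiles differ in more than GC content. ERV3-1 overlaps ZNF117 on chromosome 7, which was itself 22.4-fold higher, and reads of the overlap could be counted for either.

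Several genes that distinguish the lines did not follow the line labels, while MUC16 did in direction, at low counts. CDKN2A, which is homozygously deleted in SKOV3, had 90.9 CPM in the SKOV3-labelled mock and 91.5 CPM in its knockout library, against 50.7 and 34.2 CPM in the OVCAR3-labelled libraries. ERBB2, amplified in SKOV3, had 58.7 and 55.9 CPM in the SKOV3-labelled mock and knockout and 73.5 and 32.1 CPM in the OVCAR3-labelled ones. MUC16, the gene of the antigen CA125 that OVCAR3 is known for, had 0.04 and 0.06 CPM in the SKOV3-labelled and 2.75 and 6.20 CPM in the OVCAR3-labelled libraries. The latter rest on 45 and 91 counts, a low level, so MUC16 is weak support for the OVCAR3 label. WT1 had a count of 0 in all 4 libraries. VIM, a mesenchymal filament gene, was at 1.95 CPM and EPCAM, an epithelial adhesion gene, at 353 CPM in the SKOV3-labelled mock. Between the mock libraries, ovarian cancer and Mullerian markers (median log2 ratio 1.00, percentile 99.99) and epithelial genes (0.46, percentile 99.96) were higher in the OVCAR3-labelled one. The lines are named below as labels of libraries.

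**Figure D1:**
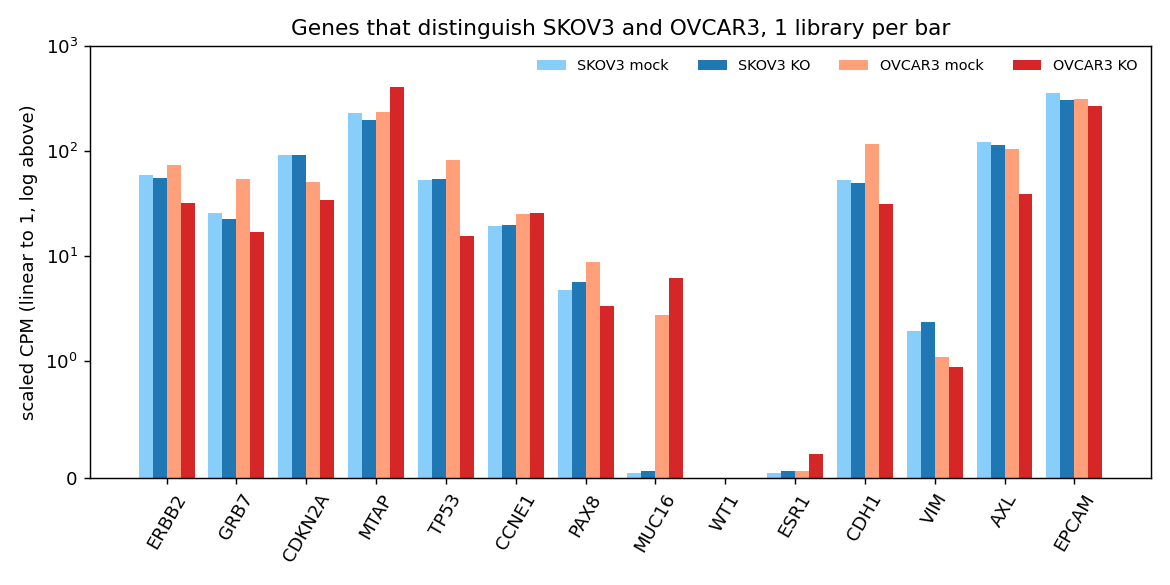
Scaled CPM (vertical axis, linear up to 1 and logarithmic above) of 14 genes that distinguish SKOV3 and OVCAR3, with 1 bar per library and no error bars. CDKN2A stood at 90.9 CPM in the SKOV3-labelled mock library, and WT1 had no bar in any library.

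In the SKOV3-labelled pair, knockout and mock were close. Hypoxia, ERK output and endoplasmic reticulum chaperone genes were lower and cell-cycle genes higher by small median shifts, with no member past the size rule. Targets of HIF, the transcription factor of the response to low oxygen, were lower in the knockout library. Of 29 measured members 28 had a log2 ratio below 0, with a median of -0.29, below all random lists (percentile 0). ALDOC, a glycolytic aldolase, had 8.21 against 16.3 CPM (-0.98, -1.29 to -0.70). ANGPTL4, a secreted inhibitor of lipoprotein lipase, had -0.88 (-1.11 to -0.65), NDRG1, a stress-response gene, -0.83 (-0.91 to -0.76), and DDIT4, an inhibitor of mTORC1 signalling, -0.57 (-0.70 to -0.45). None of the 29 passed the size rule of 2-fold.

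Genes switched on by ERK signalling were lower as well in SKOV3, 17 of 22 members with a median of -0.21 (percentile 0). DUSP5, a phosphatase of nuclear ERK, had 248 against 394 CPM (-0.67, -0.73 to -0.62), the growth factor gene AREG had -0.47 (-0.51 to -0.43) and the feedback inhibitor SPRY1 -0.54 (-0.94 to -0.17), while SPRY2, of the same family, had 0.47 (0.12 to 0.83). Endoplasmic reticulum chaperones were lower in 18 of 19 members with a median of -0.18 (percentile 0.02), led by HSPA5, the chaperone BiP, at 564 against 752 CPM (-0.42, -0.45 to -0.38), and with HSP90B1 at -0.26 (-0.30 to -0.23). Genes of invasion and matrix remodelling had a median of -0.15 with 17 of 22 members below 0 (percentile 0.10), among them the integrin gene ITGA3 at -0.37 (-0.42 to -0.32) and PLAU, encoding urokinase, at -0.34 (-0.48 to -0.21). Epithelial genes had a median of -0.10, with 17 of 25 below 0 (percentile 1.74). Tight junction genes OCLN, at -0.30 (-0.54 to -0.07), and CLDN4, at -0.20 (-0.28 to -0.12), were lower, and MAL2, an apical transport gene, was higher at 0.25 (0.21 to 0.30).

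Cell-cycle genes were higher in the SKOV3-labelled knockout library. The G2/M list had 48 of 54 members above 0 with a median of 0.21, and the S-phase list 35 of 42 with a median of 0.19, both above all random lists (percentile 100). POLD3, a DNA polymerase delta subunit, had 43.4 against 25.3 CPM (0.78, 0.62 to 0.94), BLM, a helicase, 0.56 (0.42 to 0.71), the inhibitor of apoptosis BIRC5 0.41 (0.33 to 0.49) and TOP2A, topoisomerase II alpha, 0.38 (0.32 to 0.44). DNA repair genes followed, 26 of 31 with a median of 0.13 (percentile 100), including BRCA1 at 0.45 (0.33 to 0.57). Replication-dependent histone genes had a median of 0.32 with 12 of 14 above 0 (percentile 99.3), such as HIST1H2AC at 0.80 (0.35 to 1.31), although histone messages can share reads between near-identical copies. With CPM of at least 5 the histone median was 0.27 and no longer called. WNT targets had a median of 0.17 (percentile 99.5), from AXIN2, a negative feedback gene of the pathway, at 0.90 (0.54 to 1.30) to MYC at -0.46 (-0.50 to -0.41). Targets of p53 had a median of 0.10 with 18 of 24 above 0 (percentile 99.7), such as MDM2, the p53 ubiquitin ligase, at 0.38 (0.34 to 0.43). Interferon-stimulated genes had a median of 0.13 with 23 of 30 above 0 (percentile 97.7), and members with at least 100 counts over the pair differed both ways, with ISG20 at -0.88 (-1.42 to -0.41) and IFIT2 at 0.44 (0.15 to 0.75). Mitochondrially encoded messages had a median of 0.30 (percentile 100) with 9 of 13 above 0, from ND2 at 0.97 (0.95 to 0.98) to COX1 at -0.34 (-0.35 to -0.33).

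By the size rule, 108 genes were higher and 100 lower in the SKOV3-labelled knockout library among 13524 measured. Poisson draws, which hold counting error only, gave medians of 19 and 20, and at most 31 and 35. Variation between cultures comes on top and was not measured in SKOV3, so the counts do not show a knockout effect by themselves. SLC7A11, the cystine transporter subunit (chromosome 4, 138164097 to 138242349), was lower at 25.3 against 51.0 CPM (-1.01, -1.18 to -0.85). The kinase gene SGK3 had -1.09 (-1.65 to -0.62) and RYBP, a Polycomb-associated gene, -0.88 (-1.35 to -0.46). Among the higher genes, the transcription factor gene STOX1 had 9.10 against 3.38 CPM (1.40, 1.02 to 1.85), the cilium gene CFAP43 1.08 (0.68 to 1.55) and DHRS2, a short-chain dehydrogenase gene, 0.94 (0.84 to 1.05). Several of the largest ratios belonged to rows that share reads with near-identical or overlapping copies and are uncertain, among them the pseudogene RPL4P4 at -3.23 (-3.83 to -2.81), RN7SL2 at -1.74 (-1.83 to -1.64), and the readthrough loci SENP3-EIF4A1 at 1.25 (0.88 to 1.67) and BIVM-ERCC5 at 1.03 (0.73 to 1.37). The counts rest on low genes: with CPM of at least 5 in 1 library they were 6 and 8. RB1, the retinoblastoma gene, had 0.05 (-0.05 to 0.15), and CCNB1, the mitotic cyclin B1, -0.09.

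**Figure D2:**
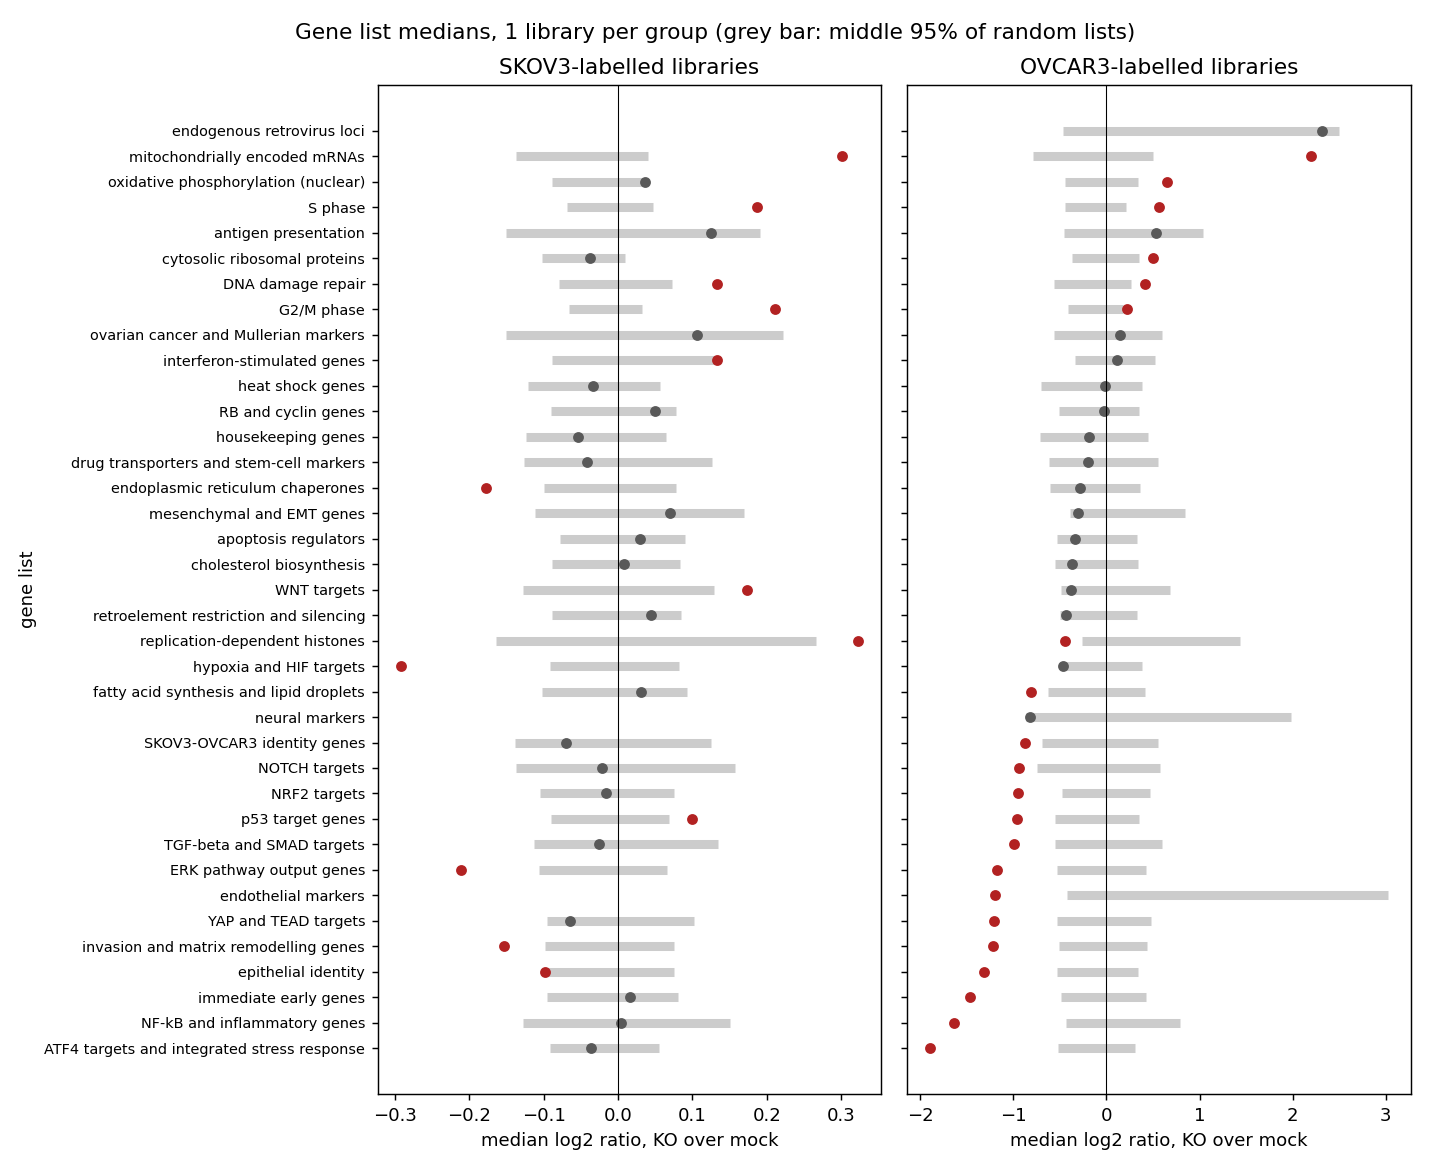
Median log2 ratio of knockout over mock (horizontal axis, differently scaled in the panels) of each gene list (vertical axis) in the SKOV3-labelled and the OVCAR3-labelled pair. Grey bars span the middle 95% of 10000 random lists and red points lie outside them, such as HIF targets at -0.29 in SKOV3 and ATF4 targets at -1.90 in OVCAR3.

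In the OVCAR3-labelled pair the knockout library differed from its mock across much of the transcriptome. Targets of ATF4, NRF2 and p53 and inflammatory, immediate early and epithelial genes were lower, and mitochondrial, ribosomal protein, S-phase and many non-coding transcripts were higher. By the size rule 3387 genes were higher and 2390 lower among 15409 measured, against Poisson medians of 38 and 43.5. The balance turns with the genes counted: with CPM of at least 5 there were 1332 higher and 2150 lower, and among protein-coding genes 1553 higher and 2222 lower. The log2 ratios had an SD of 1.01 over 10677 well-counted genes, against 0.209 in SKOV3. The knockout library also stood apart in composition. Mitochondrial rows took 21.9% of its counts against 5.93% in its mock, and the 10 highest rows 20.9% against 6.89%. The nuclear RNA NEAT1 had 1501 against 143 unscaled CPM. Long non-coding RNA genes had a median log2 ratio of 1.67 and pseudogenes 1.90, against -0.03 for protein-coding genes. Among protein-coding genes the ratio went with GC content, with a Spearman correlation across genes of -0.42 and medians from 0.47 to -0.71 across 5 groups of rising GC content. Lists below are therefore given with their percentile among random lists matched on GC content too, and their median after the trend on GC content and length was removed, where enough members had a GC value. Ratios of single genes are without this removal unless stated, and the removal moved some toward 0 and some away from it.

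**Figure D3:**
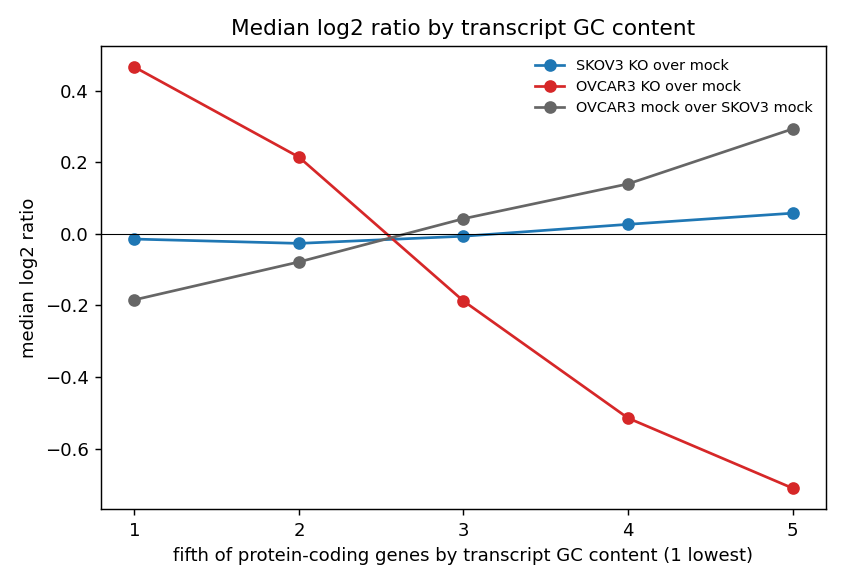
Median log2 ratio (vertical axis) of protein-coding genes in 5 equal groups by transcript GC content (horizontal axis, 1 lowest). The line for OVCAR3 knockout over mock runs from 0.47 down to -0.71, that for SKOV3 from -0.01 to 0.06, and that for the mock libraries of OVCAR3 over SKOV3 from -0.18 to 0.29.

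Targets of ATF4, the transcription factor of the integrated stress response, were the lowest list in OVCAR3. Of 27 members 26 were below 0 and 20 past 2-fold, with a median of -1.90 (percentile 0, matched on GC 0, trend removed -1.64). GDF15, a secreted stress factor, had 82.0 against 1574 CPM (-4.26, -4.35 to -4.18), SLC7A5, an amino acid transporter gene, -3.23 (-3.30 to -3.16), and TRIB3, a pseudokinase gene, -3.13 (-3.28 to -2.99). In the mock libraries the same list was higher in OVCAR3 than in SKOV3, by a median of 1.51. NF-kB and inflammatory genes had a median of -1.64 with 14 of 16 below 0 (percentile 0, matched on GC 0, trend removed -1.76), including the subunit gene NFKB2 at -2.52 (-2.64 to -2.41) and the chemokine gene CXCL8 at -2.20 (-2.57 to -1.89). The NF-kB median was -0.90 with no filter and -0.84 with CPM of at least 5, and the list was called low in both. Immediate early genes had a median of -1.47 with 22 of 23 below 0 (percentile 0, matched on GC 0.035, trend removed -1.25), such as JUN at -2.75 (-2.90 to -2.61) and ATF3 at -2.77 (-2.98 to -2.59). NRF2 targets, which respond to oxidative stress, had a median of -0.95 (percentile 0.03, matched on GC 0.26, trend removed -0.98), with OSGIN1 at -3.77 (-4.18 to -3.45) and HMOX1, heme oxygenase, at -2.42 (-2.79 to -2.11). Targets of p53 had 19 of 24 members below 0 and a median of -0.96 (percentile 0.02, matched on GC 0.17, trend removed -0.71), including CDKN1A, the cell-cycle inhibitor p21, at 110 against 941 CPM (-3.10, -3.17 to -3.02). GDF15 is in this list too.

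Signalling and adhesion genes were also lower in the OVCAR3-labelled knockout library. ERK output genes had a median of -1.18 with 19 of 22 below 0 (percentile 0, matched on GC 0, trend removed -1.12), with FOSL1 at -2.73 (-2.89 to -2.59) and the receptor gene EPHA2 at -2.70 (-2.78 to -2.63). Genes of YAP and TEAD had 20 of 21 below 0, a median of -1.21 (percentile 0, matched on GC 0, trend removed -0.96), and ANKRD1 alone past the rule upward, at 3.54 (2.84 to 4.86). Invasion and matrix genes had a median of -1.21 with 18 of 23 below 0 (percentile 0, matched on GC 0.01, trend removed -1.06), including the laminin gene LAMB3 at -4.17 (-4.38 to -3.98). Epithelial genes had 22 of 24 below 0 and a median of -1.31 (percentile 0, matched on GC 0.11, trend removed -0.92), such as KRT19 at -2.57 (-2.61 to -2.53) and ELF3 at -2.20 (-2.32 to -2.08). TGF-beta targets had a median of -0.99 (percentile 0.06, matched on GC 0.975, trend removed -0.73), with PMEPA1 at -3.02 (-4.18 to -2.33). The lists of lipid synthesis genes (-0.81, percentile 0.65), NOTCH targets (-0.94, percentile 0.72), histones (-0.44, percentile 0.95), line identity genes (-0.88, percentile 0.60) and endothelial markers (-1.19, percentile 0.20) were low, but not among lists matched on GC, where their percentiles were 4.96, 21.2, 3.61, 4.64 and 2.56. With the trend removed the medians were -0.47 for lipid synthesis, -0.69 for NOTCH, -0.51 for identity and -0.75 for endothelial genes, and histones had no such value. With CPM of at least 5 the histone median was -1.14. With no filter the endothelial median turned to 0.37, and the identity list, at -0.57, was no longer called. FASN, fatty acid synthase, had -3.24 (-3.32 to -3.17), HES1, a NOTCH target, -1.39 (-1.57 to -1.22), and EGFL7, an endothelial factor, -1.19 (-1.35 to -1.05).

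Mitochondrially encoded messages were higher in OVCAR3, 13 of 13 with a median of 2.19 (percentile 100), such as COX1 at 38620 against 6201 CPM (2.64, 2.63 to 2.65). Fewer than 5 of them had a GC value, so no GC match was made. Nuclear genes of oxidative phosphorylation had 25 of 30 above 0 and a median of 0.64 (percentile 100, matched on GC 100, trend removed 0.19), with COX7C at 1.27 (1.20 to 1.34, trend removed 0.51) and SDHA at -1.38 (-1.51 to -1.26). Ribosomal protein genes had 33 of 36 above 0 and a median of 0.50 (percentile 99.96, matched on GC 100, trend removed 0.47), led by RPS24 at 1.10 (1.07 to 1.13). S-phase genes had a median of 0.57 with 33 of 42 above 0 (percentile 100, matched on GC 100, trend removed 0.34), including CCNE2, cyclin E2, at 2.33 (2.09 to 2.62, trend removed 1.67) and the replication factor gene GINS2 at 1.40 (1.21 to 1.60, trend removed 1.47). DNA repair genes had a median of 0.41 (percentile 99.9, matched on GC 98.1, trend removed 0.23), with the recombination gene XRCC2 at 1.87 (1.62 to 2.14) and FANCA at 1.82 (1.67 to 1.97). The G2/M list was high at 0.22 (percentile 98.7) but not among lists matched on GC (90.6), and its median was -0.13 with the trend removed. Its largest ratios were below 0, with CDC20 at -2.09 (-2.21 to -1.98).

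Beyond the lists, the lowest named genes in OVCAR3 were SPRR2D at 1 count against 230 (-6.27, -13.0 to -5.20), the neuropeptide precursor gene VGF at 6.13 against 160 CPM (-4.68, -5.03 to -4.40), and the circadian clock genes NR1D1 at -4.62 (-4.80 to -4.47) and PER1 at -3.97 (-4.16 to -3.80). The highest were mainly rows with almost no mock counts. CCDC180 had 137 counts against 0, at least 50.9-fold higher against a floor of 3 counts in the mock library, and P2RY11 127 against 0, at least 47.2-fold. DYX1C1-CCPG1, a readthrough locus, had 135 against 0, 50.2-fold by that floor (lower limit 5.33). The zinc finger gene ZNF154 had 4.28 (3.63 to 5.52). RB1 had 38.4 against 64.5 CPM (-0.75, -0.90 to -0.60) and CCNB1 148 against 125 CPM (0.24, 0.16 to 0.33), and with the trend on GC content and length removed these were -1.30 and -0.11. NUPR1, a stress-response gene, had counts of 0 and 0 in SKOV3 and of 6 and 3 in OVCAR3 in mock and knockout, so no difference was detectable at this depth.

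Across both lines, few genes differed alike. SLC7A11 was lower in both, at -1.01 and at -1.06 (-1.15 to -0.96), in SKOV3 and OVCAR3 in this order. ANGPTL4 had -0.88 and -1.51 (-1.81 to -1.23), NDRG1 -0.83 and -2.20 (-2.27 to -2.13), DUSP5 -0.67 and -2.18 (-2.26 to -2.10), and ERRFI1, a feedback inhibitor of the EGF receptor, -0.63 (-0.65 to -0.60) and -1.75 (-1.79 to -1.71). Higher in both were AXIN2 at 0.90 and 1.37 (1.11 to 1.65), FAM111B, a protease gene, at 0.86 (0.70 to 1.04) and 1.54 (1.24 to 1.88), POLD3 at 0.78 and 0.84 (0.61 to 1.08), and the mitochondrial messages ND2 at 0.97 and 1.02 (1.01 to 1.03) and CYTB at 0.91 (0.89 to 0.92) and 1.53 (1.51 to 1.54). With the trend removed, the OVCAR3 ratio of SLC7A11 was -1.71 and that of FAM111B 0.91. Of the gene lists, 4 were high in both lines (S phase, G2/M, DNA repair and mitochondrial messages) and 3 were low in both (epithelial, invasion and ERK output genes). G2/M was not high in OVCAR3 among lists matched on GC content (percentile 90.6), and its median there was -0.13 with the trend removed.

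edgeR's quasi-likelihood test over both lines called 0 of 13670 genes at an adjusted p of 0.05. At an unadjusted p under 0.05 there were 140 genes, where chance alone gives 683.5. DESeq2 and limma-voom also called 0 genes, with 412 and 306 at an unadjusted p under 0.05. The smallest p, 0.00597 (adjusted p = 0.956), was that of GPR75-ASB3, a readthrough locus that overlaps other genes. No member of any list was called, adjusted over all genes or adjusted over the list alone. The lines' log2 ratios had a Pearson correlation of -0.06 and a Spearman correlation of 0.03 across 13278 genes, which are not independent replicates, and 51.7% had the same sign. By the size rule 24 genes were higher in both lines, where independent lists give 9.39 (two-sided Fisher's exact test, p = 7.17e-06), and 4 were lower in both, where independent lists give 15.0 (p = 0.00083). The 4 lower were SLC7A11, GATAD2B, GPR75-ASB3 and RAB43, of which the last 3 had no more than 133 counts in any library. In opposite directions 61 genes passed it. Both overlaps rest on low genes: with CPM of at least 5 there were 0 higher and 1 lower in both (Fisher's exact test, p = 1 for each). Only 2 higher and 6 lower genes of SKOV3 entered there, where independent lists give 0.145 and 1.17. The agreement of well-expressed genes past the rule therefore cannot be judged from it. Camera with a preset correlation of 0.01 called 18 of 34 lists, with the smallest adjusted p for mitochondrial messages (6.61e-09, upward) and ATF4 targets (1.32e-08, downward). That setting takes genes as nearly independent, and a call can come from 1 line. ATF4 targets had a median of -0.04 in SKOV3 (percentile 30.1) and of -1.90 in OVCAR3, so their call shows no shared decrease. Mitochondrial messages had medians of 0.30 and 2.19. None of the 18 held with an estimated correlation, where the smallest adjusted p = 0.684, and fry called none (smallest adjusted p = 0.697). Both rest on 1 residual degree of freedom per gene, with estimated correlations from below 0 to 1. They had little power, so their lack of calls cannot decide whether a list differs.

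**Figure D4:**
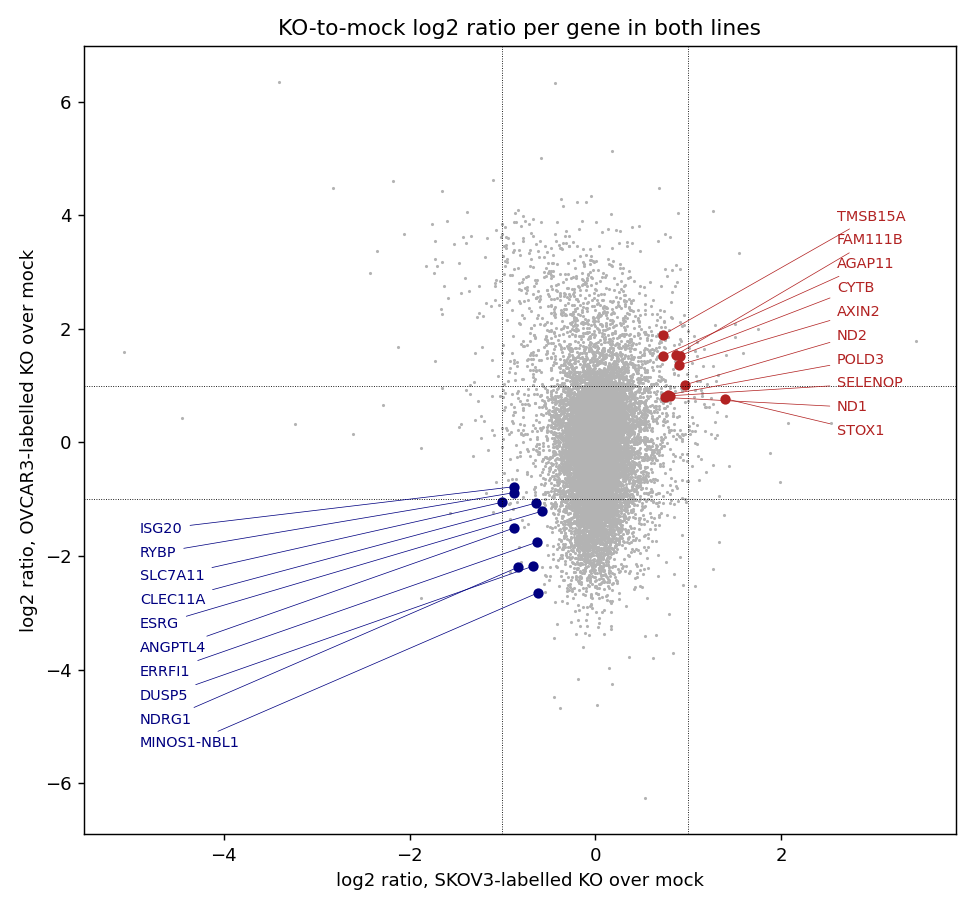
Log2 ratio of knockout over mock per gene in the SKOV3-labelled (horizontal axis) and the OVCAR3-labelled pair (vertical axis), 1 point per gene for 13278 genes. Coloured points are the 10 genes per direction that differ most alike, and the cloud has a Pearson correlation of -0.06.

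Between the line labels, PRF1, CLSTN2, TNFRSF6B and APOBEC3G were higher in the OVCAR3-labelled libraries of both genotypes, and LOC283352 was lower. The mock libraries differed less from each other (SD of the log2 ratios 0.641) than the OVCAR3 knockout from its mock (1.01). edgeR's line coefficient called 5 of 13670 genes at an adjusted p of 0.05, with 1656 at an unadjusted p under 0.05. The genes were PRF1, which encodes perforin (35.5 and 21.4 CPM in OVCAR3 mock and KO against 1.20 and 0.76 in SKOV3, log2 4.84, adjusted p = 0.0347), the calsyntenin gene CLSTN2 (4.82, adjusted p = 0.0347), the decoy receptor gene TNFRSF6B (4.10, adjusted p = 0.0362), the cytidine deaminase and retroelement restriction gene APOBEC3G (7.18, adjusted p = 0.0362), and LOC283352, with counts of 216 and 172 in SKOV3 and of 0 in both OVCAR3 libraries (adjusted p = 0.0432). With DESeq2 size factors or without the block 0 genes were called, and with DESeq2 itself 186.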

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

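Opposite differences in the 2 labelled lines picked out 5 results, and with 1 library per group none of these differences between the lines was tested. RN7SL2 and RN7SL1, near-identical copies of the RNA of the signal recognition particle, had log2 ratios of -1.74 and -1.34 in SKOV3 and of 2.99 and 3.63 in OVCAR3. CCDC180 had -3.41 in SKOV3 and 6.35 in OVCAR3, values that depend on the prior count because a library stands at 0 in each pair, and the bounds are at least 5.82-fold lower and at least 50.9-fold higher. The median of p53 targets was 0.10 in SKOV3 and -0.96 in OVCAR3, and that of replication-dependent histones 0.32 and -0.44. With CPM of at least 5 the histone medians were 0.27, no longer called high in SKOV3, and -1.14. Among lists matched on GC content the histone list was not low in OVCAR3 (percentile 3.61).

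A pattern weighed is that the OVCAR3 KO library stands far from its mock, where the predictions for GC bias and genomic DNA were written before their tests, and that for a shared knockout effect after its result was seen. Of the protein-coding genes past the size rule, 67.6% stayed past it once the trend on GC content and length was removed. This trend may thus account for part of the difference in these genes but not for all of it. It was fitted per gene on the longest transcript, so a GC or length bias of another form was not tested and stays open. Long non-coding RNA genes and pseudogenes were outside this test. Reads spread evenly from genomic DNA are an unlikely main cause, since olfactory receptor genes outside chromosome 11 gained 0.00859 of the median read density gained by 206 long non-coding RNA genes past the size rule upward with a known length, and 0.0173 of that of all 462 measured ones (added after the result was seen), although olfactory rows above 0 numbered 49 against 19 and OR52D1 on chromosome 11 had 171 counts against 17. A strong effect alike in both lines is not borne out by the Pearson correlation of the lines' ratios (-0.0555, and 0.0907 with the trend removed), while the Spearman correlation of 0.17 and the 57.1% of genes with the same sign after that removal leave a weak one open. The OVCAR3 mock itself departed from the SKOV3 mock in some lists, such as ATF4 targets (median log2 ratio 1.51, percentile 100). In others, such as mitochondrial messages (0.08, percentile 77.9), it did not. A difference in RNA or library preparation of the OVCAR3 knockout or mock library and a knockout effect in OVCAR3 cells alone remain open. Only further libraries of both groups could separate them.

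Another pattern is that CDKN2A, ERBB2 and VIM do not follow the line labels as known for these lines, although MUC16 does in direction, at low counts. The tests of this pattern were chosen after the result was seen. CDKN2A at 90.9 CPM in the SKOV3-labelled mock library is what cells other than SKOV3 would give, and an exchange of the 2 line labels would leave it under 1 CPM in the OVCAR3-labelled mock, where it had 50.7 CPM. A mixture of the 2 lines was first counted as ruled out by ERBB2 (log2 0.32, OVCAR3-labelled over SKOV3-labelled mock). That test was replaced by the exchange test after its result was seen, because even mixing would leave ERBB2 alike. Even mixing would leave other genes alike too, but 578 were higher and 262 lower under the OVCAR3 label by 2-fold in both genotypes. Of 13670 genes, 1201 were higher and 749 lower between the mock libraries, and 2247 and 2213 between the knockout libraries. Independent lists of these sizes would share some genes too. Across genes the line ratios of mock and knockout had a Pearson correlation of 0.31. LOC283352 had 216 and 172 counts in the SKOV3-labelled libraries and 0 in both OVCAR3-labelled ones. These values argue against an even mixture, while an uneven one was not tested and stays open. By a cut of at least 10 CPM against under 0.5 CPM, 1 gene, APOBEC3G, separated the labels, which 1 cell background could also give, but LOC283352 (9.60 and 10.9 CPM against 0) just missed the cut and 578 genes were higher and 262 lower by 2-fold in both genotypes, so 1 background is left open. No biological explanation was tested, and DNA profiling of the cultures is the test these counts do not replace.

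A further pattern is the low HIF target list in the SKOV3 KO library, with both predictions written before the tests. Its percentile was 0 among random lists matched on GC content, so GC content does not account for it. Whether the knockout lowers the list alike in both lines cannot be told apart from no such effect. In OVCAR3 its percentile was 4.96, above the 2.5 that the prediction had set as the bound against a shared effect, but after the result was seen this bound was judged wrong and the verdict changed. The list's shift from random lists was -0.30 in SKOV3 and -0.32 in OVCAR3, while the middle 95% of random lists in OVCAR3 reaches to -0.38 from their median, so a shift of the same size could not pass there.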

How the results depend on the processing

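Of the main results under the alternatives, 80 stayed alike, 20 moved and 9 were weaker. Those counted alike include overlaps of the lines whose numbers changed. From 24 genes higher and 4 lower in both, no filter gave 388 and 39, where independent lists give 274 and 135. A prior count of 5 gave 13 and 3. The correlation of the lines, near 0, counts as alike when it moves by less than 0.1, and it turned from -0.0555 to 0.0365 with CPM of at least 5 and to 0.0320 with a mean CPM of at least 10. Of the other results 265 stayed alike, 9 were weaker and 1 reversed. With no filter, genes higher and lower numbered 1097 and 1173 in SKOV3, and 8078 were higher in OVCAR3, because rows of few counts enter. With CPM of at least 5 they numbered 6 and 8 in SKOV3, and 1332 were higher in OVCAR3, because fewer genes are measured. A prior count of 5 left 71 higher in SKOV3, since it shrinks low genes. A fold of 1.5 gave 505 and 379 in SKOV3 and 5086 and 3928 in OVCAR3, and a fold of 3 gave 13 and 36 in SKOV3 and 939 lower in OVCAR3, by construction.

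Of the genes shared by both lines, 0 higher and 1 lower were left with CPM of at least 5, and 0 and 1 with a mean CPM of at least 10, where fewer genes are measured. With the trend on GC content and length removed, the correlation of the lines was 0.0907 and 3 genes were lower in both (Fisher's exact test, p = 0.791). This alternative keeps protein-coding genes alone, and these without the trend removed already gave a correlation of 0.0368 and 4 lower (p = 0.637). The line difference called 0 genes with DESeq2 size factors, 194 with no filter, 98 with CPM of at least 5, 3 with robust edgeR, 186 with DESeq2, 2 with limma-voom and 0 with no block; the cause was not tested. Camera with an estimated correlation and fry called 0 lists each. With 1 residual degree of freedom per gene both had little power, so this cannot decide whether the lists differ. The endothelial list in OVCAR3 had a median of 0.37 with no filter, where more members enter.

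Without a scaling factor the median OVCAR3 ratio shifted by -0.11. The knockout test over both lines called 0 genes under each alternative run for it that kept both knockout libraries. It was not run without a scaling factor. The alternative without OVCAR3 KO replicate 1 takes the lone knockout library to vary like the mock libraries, so its count is not used here. Leaving out a line leaves no residual degrees of freedom, so the ratio of the other line is then a value with no test. The line block pairs each knockout with its mock, and no pairing by replicate was made, because the groups share only replicate 1. Depth limits genes under the floor of 3 counts, and genes under 5 CPM supply most of those past the size rule in SKOV3.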

Other observations

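Other gene lists lay inside the range of random lists. In the SKOV3-labelled pair 21 of 34 lists did so, among them ATF4 targets (-0.04, percentile 30.1), immediate early genes (0.02, percentile 71.0), cholesterol synthesis genes (0.01, percentile 61.4) and ribosomal protein genes (-0.04, percentile 64.2). In the OVCAR3-labelled pair 16 of 37 did, among them interferon-stimulated genes (0.11, percentile 50.8), antigen presentation genes (0.53, percentile 74.4), heat shock genes (-0.02, percentile 57.0) and genes of RB and the cyclins (-0.02, percentile 54.9). For lists of unrelated genes, 1.7 and 1.85 would lie outside the range. Members of these lists can vary together and lists share members, so more can lie outside from any difference between cultures. Fibroblast and leukocyte markers had too few measured members for a percentile, with 2 and 3.

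Between the mock libraries, OVCAR3-labelled over SKOV3-labelled, ATF4 targets (median log2 ratio 1.51, percentile 100) and NRF2 targets (0.61, percentile 100) were higher, and S-phase (-0.54, percentile 0), heat shock (-0.59, percentile 0.03) and nuclear oxidative phosphorylation genes (-0.40, percentile 0.14) were lower. These ratios went with GC content, with a Spearman correlation across genes of 0.26. ATF4 and NRF2 targets, high in the OVCAR3 mock, were low in the ratio of OVCAR3 knockout over mock, and S-phase and oxidative phosphorylation genes, low in it, were high there. Both ratios share the OVCAR3 mock library, so these opposite directions are not independent. Each group had 1 library, and no explanation of these differences was tested.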
